A study of Mus musculus with 18 samples.

How the data were processed

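Gene expression was measured on 18 Affymetrix arrays, in 6 groups of 3 arrays. The groups are 3 subsets of colon lamina propria cells, sorted from untreated mice and from mice given dextran sulfate sodium (DSS). Per the labels' protocols, the mice were BALB/c, 8 weeks old, and the DSS dose was 2%. The same labels state that lamina propria cells were freed with collagenase and sorted from an MHC+CD11chigh gate. They also state that 5 ng of total RNA was amplified with the Ovation Pico kit, labelled with the Encore biotin kit and hybridized as 5.5 ug of single-stranded DNA.

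The deposited table holds log2 expression values, 1 value per probe set and array, made by RMA per the submitters' processing notes. RMA corrects background, normalizes by quantiles and summarizes the probes of each probe set. No version of it was given in the sources used here. The values were used as deposited. They ran from 1.07 to 13.16, and the array medians lay between 3.99 and 4.09. Background correction could not be varied from these values, and the labels name no array batch apart from the experiment number.

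Of 34760 probe sets, 21640 carried 1 gene symbol, 1321 carried several and 11799 carried none, and only those with 1 symbol were used. Of these, 21553 matched the reference gene table by gene identifier. That table's assembly is GRCm38.p6, and it served for names and synonyms only. The files used here name no genome build, so no coordinates are printed. They represent 19937 genes. A probe set was kept if its value lay above the 40th percentile of all values, a level of 3.51, in at least 3 of the 18 arrays. Where several probe sets of a gene were kept, the one with the highest mean over the 18 arrays stood for it, and 14003 genes were tested. The filter level is a percentile and not a measured background, and the values carry no detection calls. A difference from a group mean under 3.51 is therefore given as a lower bound.

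All 18 arrays entered a single linear model in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with a mean for each group and an empirical Bayes estimate of the spread. The 13 comparisons, all tested two-sided, were the 3 pairs of subsets in untreated mice, the same 3 pairs after DSS, DSS against untreated in each subset, the 3 differences between subsets in that change (interactions), and DSS against untreated over all subsets. The last was fitted on the mean of the 3 arrays of each of the 6 experiments, so that an experiment counted once. A gene was called at an adjusted p under 0.05 by the Benjamini-Hochberg method over the genes tested. Errors beside log2 differences are limma's standard errors.

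The experiment number in the array titles was treated as pairing the subsets of a condition. The check of this used correlations, across genes, of the residuals of arrays that share a number. In untreated cells the 9 pairs ran from -0.03 to 0.32 with a median of 0.25, 7 of the 9 pairs exceeded 0.1, and the median of the 18 other pairs was -0.12. In DSS cells the 9 pairs ran from 0.11 to 0.31 with a median of 0.18, and the 18 other pairs had a median of -0.13. Of 9 untreated arrays 8 were closest to an array of their own number, and so were 9 of 9 DSS arrays. Genes are not independent replicates. The number was therefore also fitted as a replicate block.

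Gene lists were fixed with the tests, the filter and the rule for naming genes before the data were examined. There are 28 lists: cDC1 programme, cDC2 programme, common DC, macrophage, monocyte, DC maturation, retinoic acid and TGF-beta, interferon-stimulated, interferon-gamma response, MHC class I presentation, MHC class II presentation, cytokines, chemokines, chemokine receptors, pattern recognition, complement and Fc receptors, cell cycle, glycolysis and hypoxia, tissue repair and matrix, immediate-early and heat shock, epithelium, B and plasma cells, T, NK and innate lymphoid cells, plasmacytoid DC, neutrophil, eosinophil and mast cell, stroma and endothelium, and erythroid. Of 528 genes on them, 464 were tested and 52 had no usable probe set. The erythroid list kept 3 genes and was counted only. The other lists were tested with camera at an inter-gene correlation of 0.01, and again with the correlation estimated from the data, adjusted over the lists of a comparison. Camera asks whether a list moved more than the other genes. The fry test was run beside it: its p asks whether the genes of a list move on balance in 1 direction, its mixed p asks whether they change in either direction, and neither compares the list with other genes.

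Named genes followed a rule. Itgae, Itgam and Itgax, which encode the sort markers CD103, CD11b and CD11c, are named throughout. The 10 called genes with the largest rise and the 10 with the largest fall were named in each comparison of 2 groups, if all 3 values of a group lay above the 3 of the other. In the subset comparisons after DSS the number was 5 each way, and in an interaction without calls it was the 3 of lowest p each way. Symbols that are only clone or model names were left out. From each list, the 4 members of lowest p in each direction could be named. Genes outside this rule are marked as chosen after their values were seen.

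The alternatives were no filter, a filter at the 60th percentile, arrays centred on their medians, quantile normalization applied again, the mean of all probe sets of a gene, limma-trend, a fit on only the groups of the comparison, the replicate block, and leaving out each array, or each experiment for the interactions and the comparison over all subsets. Leaving arrays, experiments or the sort genes out of the list tests was added after the results were seen. The closing section gives their effect.

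The scripts were tested on simulated data of 14003 genes, 200 of them changed. For untreated CD103+CD11b- against CD103-CD11b+ cells, 22.4% of the genes changed by a log2 of 0.5 were recovered, 82.1% at a log2 of 1 and 100% at a log2 of 2. For DSS against untreated in CD103+CD11b- cells the shares were 28.4%, 76.1% and 100%. For the interaction of CD103+CD11b- with CD103-CD11b+ cells they were 6%, 52.2% and 95.5%. For DSS against untreated over all subsets they were 64.2%, 97% and 98.5%. False calls were 7.48%, 6.21%, 8.11% and 2.81% of the calls in these 4 comparisons, so the first 3 exceeded the 5% aimed at in this simulation. A list shifted by 0.5 was called in each of these 4 comparisons, and 0 other lists were called. Simulated values do not show how often lists are falsely called in the real data.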

Results

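The arrays measured gene expression in MHC+CD11chigh cells of the mouse colon lamina propria, sorted by CD103 and CD11b into CD103+CD11b-, CD103+CD11b+ and CD103-CD11b+ cells. Each subset was taken from untreated mice and from mice given dextran sulfate sodium (DSS), a polymer that injures the colon epithelium and causes colitis, with 3 arrays for each of the 6 groups. Replicates 1 to 3 are the untreated experiments and replicates 4 to 6 the DSS experiments, each with 1 array of every subset. The labels do not say how many mice gave the cells of an array, nor whether replicates are separate animals, so p-values measure the spread between these samples. Because no experiment held both conditions, the experiments and the DSS treatment cannot be told apart. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.166. Across all probe sets, which are not independent replicates, arrays of a group correlated at 0.965 to 0.982. The first principal component held 29.9% of the variance, and CD103+CD11b- arrays lay between -29.9 and -24.4 on it while all other arrays lay between 6.2 and 24.8.

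The first comparison asked which genes separate untreated CD103+CD11b- cells from untreated CD103-CD11b+ cells. Genes of type 1 conventional dendritic cells (cDC1) were higher in CD103+CD11b- cells, and genes of type 2 conventional dendritic cells (cDC2), macrophages, complement and Fc receptors were lower. Xcr1 (probe set 10597996), the receptor for the chemokine XCL1, averaged 9.62 ± 0.12 (SD, n = 3) in CD103+CD11b- cells and 5.38 ± 0.22 (SD, n = 3) in CD103-CD11b+ cells, a log2 difference of 4.24 ± 0.21 (SE). Clec9a (probe set 10542181), a receptor for actin exposed on dead cells, differed by 3.94 ± 0.26. The sort genes followed the labels: Itgae (probe set 10378286) was higher by 3.01 ± 0.13, Itgam (probe set 10557862) differed by -2.79 ± 0.20 and Itgax (probe set 10557895) by -0.73 ± 0.16. In all, 1447 of 14003 genes were called, 702 higher and 745 lower in CD103+CD11b- cells. Of the called genes, 1421 had all 3 values of a group above the 3 of the other. Among all genes tested 22.6% were so separated, where chance gives 10%.

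Other genes higher in CD103+CD11b- cells were the orphan receptor Gpr141b (probe set 10407982) at 4.84 ± 0.22, the formyl peptide receptor relative Gpr33 at 4.14 ± 0.29, the mitochondrial uncoupling protein Ucp1 at 3.33 ± 0.27 and the collagen prolyl hydroxylase P3h2 at 3.11 ± 0.31. The kinase Lrrk2 differed by 3.11 ± 0.13, the protease inhibitor Stfa2 by 3.05 ± 0.34 and Tssc4 by 2.90 ± 0.24. Lower in CD103+CD11b- cells were the galactose-binding lectin Mgl2 (probe set 10377774), which averaged 4.46 ± 0.27 against 9.08 ± 0.29 and differed by -4.62 ± 0.21, and its relative Clec10a at -2.81 ± 0.25. Il22ra2, the soluble receptor that neutralizes interleukin 22, differed by -4.30 ± 0.25. The lectin Cd209a differed by -3.36 ± 0.24, the inhibitory receptor Pilra by -3.32 ± 0.32, the collagenase Mmp13 by -3.14 ± 0.38 and the tetraspanin relative Tm4sf19 by -3.06 ± 0.26. Inhba, which encodes the subunit of activin A, differed by -3.03 ± 0.24, the complement gene C1qa by -3.02 ± 0.18 and the glycoprotein gene Gpnmb by -2.99 ± 0.38.

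Of 19 tested genes of the cDC1 programme, 18 were higher in untreated CD103+CD11b- than in CD103-CD11b+ cells and 0 lower (19 and 0 adjusted over the list alone; camera adjusted p = 4.59e-31), among them the endocytic receptor Ly75 at 2.08 ± 0.16. The cDC2 programme had 13 of 17 genes lower and 2 higher (13 and 2 adjusted over the list alone; 2.28e-17). Sirpa differed by -2.62 ± 0.14 and the transcription factor Zeb2 by -2.38 ± 0.17. The higher members were Clec12a at 2.43 ± 0.22 and the lipid-presenting Cd1d1 at 0.79 ± 0.18. The macrophage list had 17 of 22 genes lower and 1 higher (18 and 1 adjusted over the list alone; 3.69e-24): the growth factor receptor Csf1r differed by -2.73 ± 0.17, and the higher gene was Timd4 at 0.74 ± 0.20, whose call was lost without 1 of 3 arrays, on only these groups or with quantile normalization again (adjusted p of up to 0.121). For complement and Fc receptors 13 of 16 genes were lower and 0 higher (14 and 0 adjusted over the list alone; 5.33e-25), with the Fc receptor Fcgr3 at -2.20 ± 0.15 and its signalling chain Fcer1g at -1.54 ± 0.11. Pattern recognition had 14 of 23 lower and 1 higher (14 and 2 adjusted over the list alone; 1.11e-11). Tlr8 differed by -2.19 ± 0.21, the lectin Clec4n by -2.54 ± 0.19, and Tlr3 was the higher gene at 1.18 ± 0.17. Tissue repair and matrix had 12 of 22 lower and 1 higher (14 and 1 adjusted over the list alone; 1.89e-14), among them the elastase Mmp12 at -2.62 ± 0.18 and the cyclooxygenase Ptgs2 at -1.48 ± 0.14. The plasmacytoid DC list had 4 of 9 genes lower and 0 higher (4 and 0 adjusted over the list alone; 0.00253), among them Cd209d at -2.16 ± 0.23 and Siglech at -1.58 ± 0.29. For Tlr8, Cd209d and Cd1d1 the lower group mean lay under the filter level of 3.51, so these differences are lower bounds. These 7 calls held with an estimated correlation, with the highest adjusted p = 0.0234 for plasmacytoid DC.

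Further lists differed between untreated CD103+CD11b- and CD103-CD11b+ cells by camera but not with an estimated correlation. Common DC had 4 of 13 genes higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.00521, adjusted p = 0.0682 with an estimated correlation), with the cytokine receptor Flt3 at 1.81 ± 0.17. Monocyte genes were split: 7 of 16 lower and 3 higher (8 and 3 adjusted over the list alone; 0.00238, adjusted p = 0.151 with an estimated correlation). The lysozyme gene Lyz1 differed by -2.29 ± 0.25, whereas the integrin Itga1 at 2.14 ± 0.23 and Treml4 at 2.08 ± 0.25 were higher. Chemokines had 8 of 22 lower and 2 higher (9 and 2 adjusted over the list alone; 2.24e-05, adjusted p = 0.0641 with an estimated correlation): Cxcl14 differed by -1.92 ± 0.22 and Ccl9 by -2.04 ± 0.24, and the interferon-gamma targets Cxcl9 at 1.08 ± 0.19 and Cxcl11 at 1.09 ± 0.19 were higher. Chemokine receptors had 5 of 15 lower and 1 higher (6 and 1 adjusted over the list alone; 0.0299, adjusted p = 0.0682 with an estimated correlation), with Ccr1 at -2.77 ± 0.27. Glycolysis and hypoxia had 5 of 20 lower and 2 higher (6 and 2 adjusted over the list alone; 0.00682, adjusted p = 0.116 with an estimated correlation), with the lactate transporter Slc16a3 at -1.5 ± 0.19. The neutrophil list had 4 of 15 lower and 1 higher (4 and 1 adjusted over the list alone; 0.0151, adjusted p = 0.151 with an estimated correlation). Its lower genes included Trem1 at -2.35 ± 0.24 and Csf3r at -1.84 ± 0.22. The call of chemokine receptors was also lost without 1 of 2 arrays (adjusted p of up to 0.0611).

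Lists without a camera call in untreated CD103+CD11b- against CD103-CD11b+ cells still held called genes. The cytokine list had 3 of 24 higher and 6 lower (3 and 6 adjusted over the list alone): Il12b, a subunit of interleukin 12, was higher by 2.41 ± 0.25 and Il15 by 1.35 ± 0.27, and Il1rn, the interleukin 1 receptor antagonist, differed by -2.01 ± 0.14 and Osm by -2.36 ± 0.23. Fry gave the cytokine list an adjusted p = 5.33e-05 for a balance downwards. DC maturation had 5 of 21 higher and 2 lower (10 and 3 adjusted over the list alone), with Relb at 0.68 ± 0.14 and Socs2 at -0.96 ± 0.20. MHC class I presentation had 5 of 18 higher and 1 lower (6 and 1 adjusted over the list alone), with the peptide transporters Tap1 at 1.32 ± 0.17 and Tap2 at 1.21 ± 0.17, and the oxidase subunit Cybb lower at -2.39 ± 0.16. MHC class II presentation had 1 of 13 higher and 3 lower (2 and 3 adjusted over the list alone), with the protease Ctss at -1.05 ± 0.13. The interferon-gamma response had 5 of 21 higher and 3 lower (7 and 3 adjusted over the list alone), and interferon-stimulated genes 3 of 23 higher and 2 lower (4 and 5 adjusted over the list alone). With the replicate block the interferon-gamma response was called higher (adjusted p = 0.0362) and the T, NK and innate lymphoid list lower (adjusted p = 0.0362). Retinoic acid and TGF-beta had 3 of 24 higher and 2 lower (3 and 2 adjusted over the list alone). Dhrs9 at 1.68 ± 0.20 and Dhrs3 at -1.26 ± 0.15 both belong to the dehydrogenase/reductase family. Immediate-early and heat shock had 1 of 23 higher and 1 lower (3 and 1 adjusted over the list alone), and the eosinophil and mast cell list 1 of 10 higher and 1 lower (1 and 1 adjusted over the list alone). The stroma and endothelium list had 0 of 18 higher and 1 lower (0 and 1 adjusted over the list alone), T, NK and innate lymphoid cells 0 of 12 higher and 1 lower (0 and 1 adjusted over the list alone), and epithelium 0 of 19 higher and 1 lower (0 and 0 adjusted over the list alone). Cell cycle, B and plasma cells and erythroid genes gave 0 calls of 23, 13 and 3 genes.

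**Figure D1:**
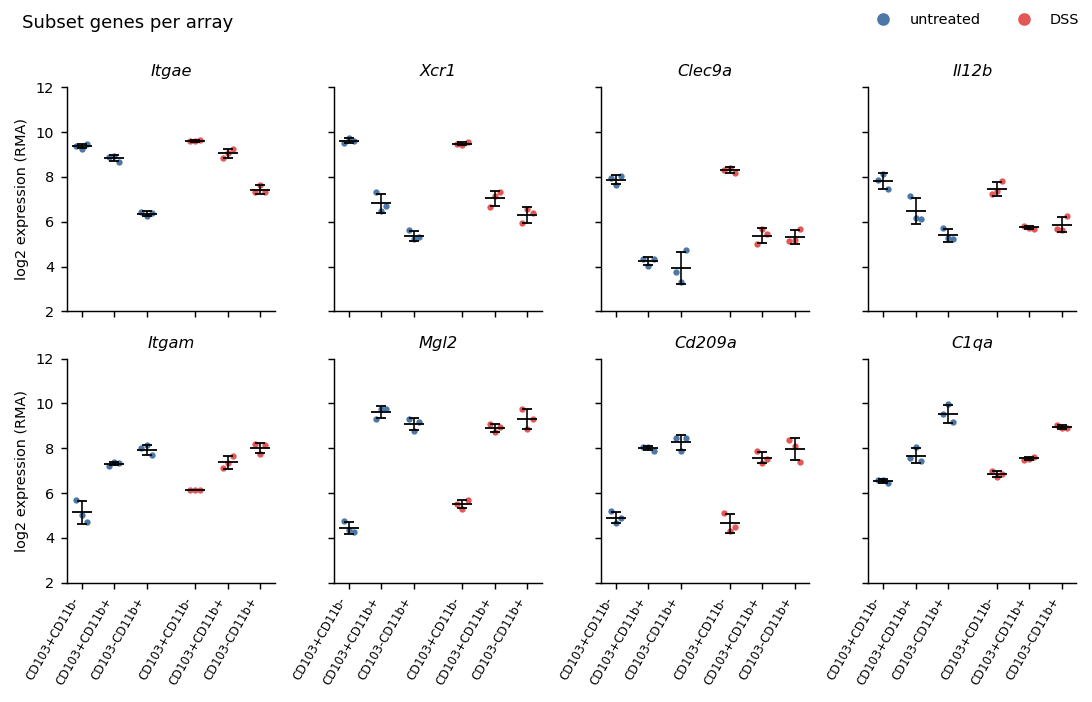
Log2 expression (RMA values) of 8 subset genes on each of the 18 arrays, in 3 subsets of untreated and DSS cells; points are arrays, and black marks are the mean with its SD (n = 3). Xcr1 averaged 9.62 in untreated CD103+CD11b- cells and 5.38 in untreated CD103-CD11b+ cells.

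Untreated CD103+CD11b- cells were next set against untreated CD103+CD11b+ cells, which share CD103 and differ in CD11b. As a group, genes of the cDC1 programme were higher in CD103+CD11b- cells, and those of the cDC2 programme were lower. Mgl2 averaged 4.46 ± 0.27 (SD, n = 3) in CD103+CD11b- cells and 9.60 ± 0.27 (SD, n = 3) in CD103+CD11b+ cells, a log2 difference of -5.15 ± 0.21. Itgam differed by -2.17 ± 0.20, Itgax by -0.45 ± 0.16 (adjusted p = 0.116) and Itgae by 0.53 ± 0.13 (adjusted p = 0.0174). The Itgae call was lost without untreated CD103+CD11b- replicate 1 or 3, without untreated CD103+CD11b+ replicate 3, or on only these groups, with an adjusted p of up to 0.0797. In all, 960 genes were called, 387 higher and 573 lower, and 948 of them were separated. The separated share was 22%, where chance gives 10%.

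In CD103+CD11b- against CD103+CD11b+ cells, the higher genes included Gpr141b at 4.01 ± 0.22, P3h2 at 3.89 ± 0.31, Clec9a at 3.64 ± 0.26, Gpr33 at 3.03 ± 0.29 and Tssc4 at 3.0 ± 0.24. Xcr1 was higher by 2.80 ± 0.21, the lysosomal amidase Naaa by 2.87 ± 0.21, Mab21l3 by 2.71 ± 0.19, Ucp1 by 2.68 ± 0.27 and Itga1 by 2.57 ± 0.23. The lower genes included Hamp, which encodes the iron regulator hepcidin, at -3.76 ± 0.38, Clec10a at -3.26 ± 0.25, Cd209a at -3.09 ± 0.24 and Cd209c at -3.02 ± 0.24, a lower bound because its lower mean lay under the filter level of 3.51. Il22ra2 differed by -2.73 ± 0.25, Pilra by -2.57 ± 0.32, the chemokine receptor Ccr1 by -2.53 ± 0.27, and Trem1 by -2.55 ± 0.24. Clec4n differed by -2.55 ± 0.19.

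Among the lists in untreated CD103+CD11b- against CD103+CD11b+ cells, the cDC1 programme had 13 of 19 genes higher and 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 3.74e-26). The cDC2 programme had 12 of 17 lower and 1 higher (12 and 3 adjusted over the list alone; 1.75e-13), with Sirpa at -2.10 ± 0.14 and the inhibitory receptor Cd300a at -2.28 ± 0.15, and Clec12a higher at 2.12 ± 0.22. For complement and Fc receptors 10 of 16 were lower and 1 higher (12 and 1 adjusted over the list alone; 6.71e-09). The positive complement regulator Cfp differed by -1.74 ± 0.21 and the integrin chain Itgb2 was higher by 0.55 ± 0.15, a call lost without any of the 6 arrays compared (adjusted p of up to 0.102). Tissue repair and matrix had 6 of 22 lower and 0 higher (10 and 1 adjusted over the list alone; 9.43e-07), with Mmp12 at -2.43 ± 0.18 and Ptgs2 at -1.60 ± 0.14. The plasmacytoid DC list had 3 of 9 lower and 0 higher (3 and 0 adjusted over the list alone; 0.00198), with Ccr9 at -1.30 ± 0.26. These 5 calls held with an estimated correlation, with the highest adjusted p = 0.0289. Macrophage genes had 7 of 22 lower and 0 higher (7 and 0 adjusted over the list alone; 0.000313, adjusted p = 0.345 with an estimated correlation), with Csf1r at -1.19 ± 0.17 and C1qa at -1.14 ± 0.18. Pattern recognition had 7 of 23 lower and 1 higher (11 and 1 adjusted over the list alone; 0.000565, adjusted p = 0.0985 with an estimated correlation), with Clec4d at -1.80 ± 0.16. The interferon-gamma response had 3 of 21 higher and 0 lower (3 and 0 adjusted over the list alone; 0.0292, adjusted p = 0.345 with an estimated correlation), namely Gbp5 at 1.26 ± 0.21, Cxcl9 and Cxcl11. Epithelium genes were lower as a list (0.0266, adjusted p = 0.539 with an estimated correlation), but only the adhesion molecule Cdh1 was called, at -1.18 ± 0.17. No call was made for cytokines, yet Il15 at 1.90 ± 0.27 and Il12b at 1.35 ± 0.25 were higher and Il1rn at -1.61 ± 0.14 was lower. The list calls of the interferon-gamma response and epithelium were lost without some single arrays (adjusted p of up to 0.0981 and 0.248).

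Untreated CD103+CD11b+ cells were then set against untreated CD103-CD11b+ cells, which share CD11b and differ in CD103. Macrophage and complement genes were lower in CD103+CD11b+ cells, and the cDC1 genes Itgae, Ly75 and Xcr1 were higher. Itgae averaged 8.84 ± 0.14 (SD, n = 3) against 6.35 ± 0.11 (SD, n = 3), a log2 difference of 2.49 ± 0.13. Itgam differed by -0.62 ± 0.20 (adjusted p = 0.103) and Itgax by -0.28 ± 0.16 (adjusted p = 0.425), neither of them called. There were 575 called genes, 330 higher and 245 lower, or 242 higher and 308 lower after quantile normalization was applied again. The count was 315 without untreated CD103-CD11b+ replicate 2 and 150 in a fit on only these groups. Of the called genes 572 were separated, and 17.4% of all genes were, where chance gives 10%.

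Higher in CD103+CD11b+ than in CD103-CD11b+ cells were the tight junction gene Cldn1 at 1.65 ± 0.22, Treml4 at 1.62 ± 0.25, Ly75 at 1.46 ± 0.16, Rtn1 at 1.44 ± 0.24, Xcr1 at 1.44 ± 0.21 and the actin-severing Scin at 1.44 ± 0.21. The catenin Ctnnd2 differed by 1.41 ± 0.18, the protease inhibitor Serpinb6b by 1.39 ± 0.14, and the isomerase Idi2 by 1.46 ± 0.37. Idi2 averaged only 3.86 ± 0.63 (SD, n = 3) in the higher group and lay under the filter level of 3.51 in the other, so its difference is a lower bound, and its call was lost without 1 of 4 arrays or on only these groups, with an adjusted p of up to 0.143. Lower were Mmp13 at -2.37 ± 0.38, the matrix protein Tgfbi at -1.94 ± 0.15, C1qa at -1.88 ± 0.18, the eotaxin Ccl24 at -1.81 ± 0.39 and the protease inhibitor Serpinb8 at -1.76 ± 0.25. Ccl24 lost its call on only these groups (adjusted p = 0.122). Dmxl2 differed by -1.76 ± 0.18, adenosine deaminase Ada by -1.76 ± 0.19, the lectin Clec4e by -1.72 ± 0.29, Lilra5 by -1.72 ± 0.31 and Tm4sf19 by -1.71 ± 0.26.

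In CD103+CD11b+ against CD103-CD11b+ cells of untreated mice, the macrophage list had 15 of 22 genes lower and 0 higher (18 and 1 adjusted over the list alone; camera adjusted p = 8.81e-29), with Csf1r at -1.54 ± 0.17 and the endotoxin receptor Tlr4 at -1.69 ± 0.21. Complement and Fc receptors had 12 of 16 lower and 0 higher (13 and 0 adjusted over the list alone; 2.46e-23), with the anaphylatoxin receptor C5ar1 at -1.63 ± 0.16 and Fcgr3 at -1.39 ± 0.15. The cDC1 programme had 7 of 19 higher and 2 lower (8 and 4 adjusted over the list alone; 0.00105): Wdfy4 was higher by 0.91 ± 0.14, and Cadm1 at -1.03 ± 0.24 and Rab7b at -0.97 ± 0.25 were lower, calls that were each lost without 1 of 3 arrays or on only these groups (adjusted p of up to 0.156 and 0.165). Pattern recognition had 6 of 23 lower and 0 higher (8 and 0 adjusted over the list alone; 7.46e-07) and tissue repair and matrix 4 of 22 lower and 0 higher (4 and 0 adjusted over the list alone; 2.23e-06), with Mmp14 at -1.36 ± 0.21 and Inhba at -1.54 ± 0.24. These 5 calls held with an estimated correlation, with the highest adjusted p = 0.035. The cDC1 list holds Itgae, whose difference the sort fixed. Without it the list's mean difference was 0.27 in place of 0.39 and still called at the fixed correlation (adjusted p = 0.0227). Common DC had 3 of 13 higher and 0 lower (6 and 1 adjusted over the list alone; 0.0016, adjusted p = 0.0654 with an estimated correlation), namely Flt3 at 1.33 ± 0.17, the transcription factor Zbtb46 at 0.89 ± 0.15 and Kmo. On only these groups Zbtb46 (adjusted p = 0.0664) and Kmo lost their calls, and Kmo also lost it without 1 of 4 arrays (adjusted p of up to 0.191). The cDC2 programme had 4 of 17 lower and 0 higher (6 and 2 adjusted over the list alone; 0.00773, adjusted p = 0.0802 with an estimated correlation), with Clec4a2 at -1.40 ± 0.19 and Zeb2 at -1.18 ± 0.17. DC maturation had 20 of 21 genes with positive differences and 1 call, Relb at 0.77 ± 0.14, which was lost on only these groups (adjusted p = 0.0576) (10 higher adjusted over the list alone; 6.54e-05, adjusted p = 0.0746 with an estimated correlation). Chemokines had 5 of 22 lower and 0 higher (5 and 1 adjusted over the list alone; 6.54e-05, adjusted p = 0.0797 with an estimated correlation), and monocyte genes 4 of 16 lower and 2 higher (4 and 2 adjusted over the list alone; 0.0016, adjusted p = 0.186 with an estimated correlation). Interferon-stimulated genes were lower as a list (0.0337, adjusted p = 0.669 with an estimated correlation) with 0 of 23 called. With the replicate block cell cycle genes were called higher (adjusted p = 0.0408). The list calls of monocyte and interferon-stimulated genes were lost without some single arrays (adjusted p of up to 0.0817 and 0.436). Untreated CD103-CD11b+ replicate 2 stood apart with a macrophage mean of 8.87 against 8.27 and 8.25, and without it the macrophage difference was -0.7 in place of -0.91.

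**Figure D2:**
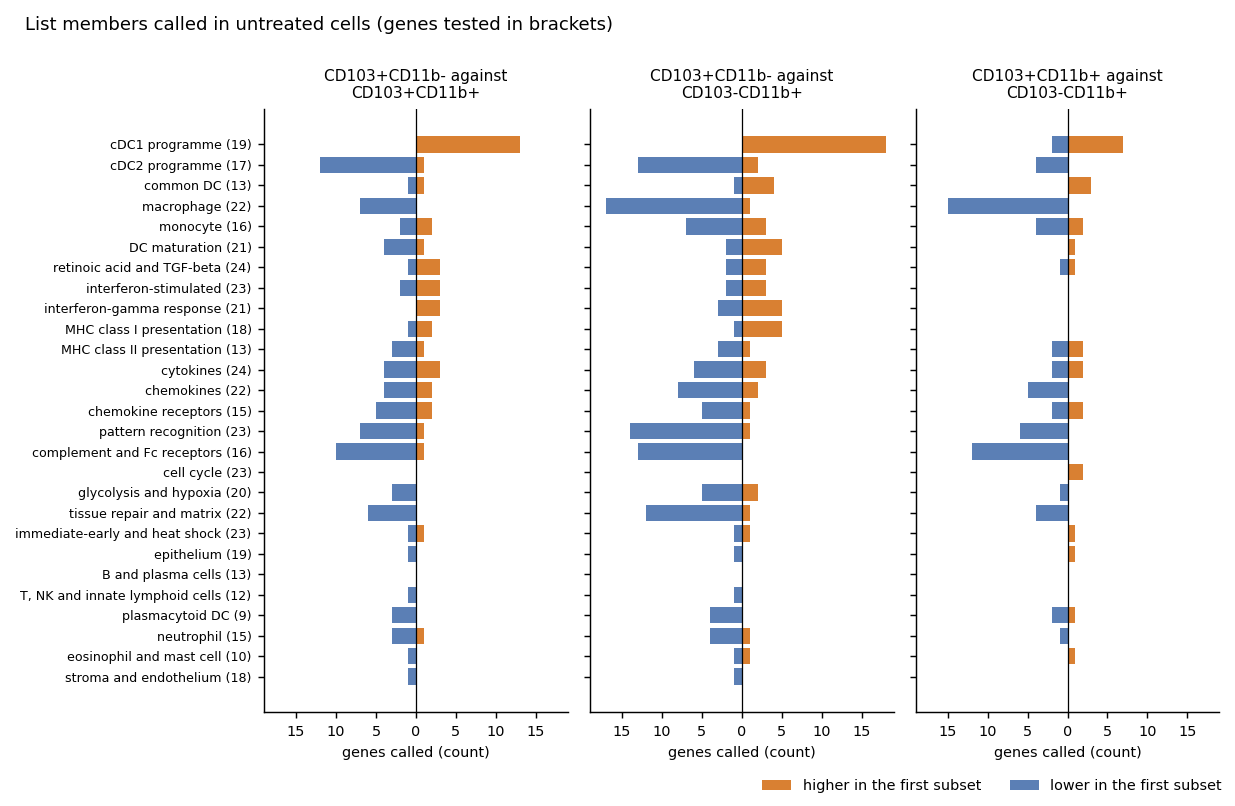
Number of genes called higher or lower in the first-named subset, for each of 27 gene lists in the 3 comparisons of untreated subsets, with the number of genes tested in brackets. The cDC1 programme had 18 of 19 genes higher in CD103+CD11b- than in CD103-CD11b+ cells.

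The same 3 subset comparisons were made after DSS, where they asked whether the subsets still differed. In CD103+CD11b- against CD103+CD11b+ cells, P3h2 was higher by 3.52 ± 0.31, Gpr141b by 3.44 ± 0.22, Tssc4 by 2.98 ± 0.24, Clec9a by 2.93 ± 0.26 and Ucp1 by 2.85 ± 0.27. Mgl2 averaged 5.50 ± 0.19 (SD, n = 3) against 8.91 ± 0.17 (SD, n = 3) and differed by -3.41 ± 0.21, Clec10a by -3.10 ± 0.25, Hamp by -2.96 ± 0.38 and Cd209a by -2.94 ± 0.24. Gp2 differed by -2.88 ± 0.65, and its call was lost without DSS CD103+CD11b- replicate 4 or DSS CD103+CD11b+ replicate 6 (adjusted p of up to 0.0607). Itgae was higher by 0.55 ± 0.13 (adjusted p = 0.0142), a call lost without DSS CD103+CD11b- replicate 6 or DSS CD103+CD11b+ replicate 4 (adjusted p of up to 0.101). Itgam differed by -1.24 ± 0.20 and Itgax by -0.26 ± 0.16 (adjusted p = 0.53). Of 834 called genes 499 were higher and 335 lower, and 832 of them were separated. The separated share was 22.8%, where chance gives 10%.

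In DSS CD103+CD11b- against CD103+CD11b+ cells, the cDC1 programme had 13 of 19 genes higher and 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 6.36e-24), and the cDC2 programme 11 of 17 lower and 2 higher (11 and 3 adjusted over the list alone; 1.93e-12). Those calls held with an estimated correlation, with the higher adjusted p = 0.000565. Tissue repair and matrix had 5 of 22 lower and 1 higher (6 and 1 adjusted over the list alone; 1.88e-06, adjusted p = 0.0527 with an estimated correlation). Complement and Fc receptors had 3 of 16 lower and 1 higher (4 and 1 adjusted over the list alone; 0.000395, adjusted p = 0.219 with an estimated correlation). Macrophage genes had 2 of 22 lower (2 adjusted over the list alone; 0.00885, adjusted p = 0.414 with an estimated correlation), C1qa at -0.69 ± 0.18 and Csf1r at -0.66 ± 0.17, and both calls were lost without some single arrays (adjusted p of up to 0.0874 and 0.117). The MHC class I list was higher (0.00729, adjusted p = 0.269 with an estimated correlation), with Tap1 at 1.13 ± 0.17, and so were the interferon-gamma response (0.00885, adjusted p = 0.251 with an estimated correlation) and common DC (0.0352, adjusted p = 0.251 with an estimated correlation). Lower were chemokine receptors (0.0189, adjusted p = 0.102 with an estimated correlation), pattern recognition (0.0451, adjusted p = 0.369 with an estimated correlation and 0.0626 with the replicate block), neutrophil (0.0102, adjusted p = 0.251 with an estimated correlation) and epithelium genes (0.00594, adjusted p = 0.414 with an estimated correlation).  The 6 list calls of MHC class I, the interferon-gamma response, common DC, chemokine receptors, pattern recognition and neutrophil genes were lost without some single arrays (adjusted p of up to 0.125).

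In DSS CD103+CD11b- against CD103-CD11b+ cells, Gpr141b was higher by 4.41 ± 0.22, the lectin Cd207 by 3.28 ± 0.30, Xcr1 by 3.18 ± 0.21, P3h2 by 3.17 ± 0.31 and Gcsam by 3.14 ± 0.21. Mgl2 differed by -3.80 ± 0.21, Il22ra2 by -3.57 ± 0.25, Cd209a by -3.32 ± 0.24, Hamp by -3.23 ± 0.38 and Clec10a by -2.74 ± 0.25. Itgae differed by 2.17 ± 0.13, Itgam by -1.89 ± 0.20 and Itgax by -0.69 ± 0.16 (adjusted p = 0.00845). The Itgax call was lost without DSS CD103+CD11b- replicate 5 or DSS CD103-CD11b+ replicate 6 (adjusted p of up to 0.0576). Of 1195 called genes 587 were higher and 608 lower, or 507 higher and 448 lower without DSS CD103+CD11b- replicate 5, and 1185 of them were separated. The separated share was 24.6%, where chance gives 10%. The cDC1 programme had 16 of 19 genes higher and 0 lower (19 and 0 adjusted over the list alone; camera adjusted p = 5.12e-30), and the cDC2 programme 12 of 17 lower and 1 higher (12 and 1 adjusted over the list alone; 4.05e-16). Macrophage genes had 15 of 22 lower and 1 higher (17 and 1 adjusted over the list alone; 2.01e-17), and complement and Fc receptors 13 of 16 lower and 0 higher (14 and 0 adjusted over the list alone; 5.83e-21). Monocyte genes had 11 of 16 lower and 2 higher (12 and 3 adjusted over the list alone; 2.29e-06), with the clotting factor gene F10 at -2.28 ± 0.32. Common DC (0.000329), pattern recognition (1.68e-07), tissue repair and matrix (3.34e-12), chemokine receptors (0.0147) and plasmacytoid DC genes (0.0139) were also called, the first higher and the rest lower, and these 10 calls held with an estimated correlation (highest adjusted p = 0.0445). Chemokines (0.000175, adjusted p = 0.0796 with an estimated correlation), glycolysis and hypoxia (0.0164, adjusted p = 0.158 with an estimated correlation), neutrophil (0.018, adjusted p = 0.168 with an estimated correlation) and epithelium genes (0.0476, adjusted p = 0.536 with an estimated correlation) were lower. With the replicate block MHC class I presentation was called higher (adjusted p = 0.0292). List calls of glycolysis and hypoxia, neutrophil and epithelium genes were lost without some single arrays (adjusted p of up to 0.531, for epithelium).

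In DSS CD103+CD11b+ against CD103-CD11b+ cells, Crisp3, which encodes a secreted cysteine-rich protein, averaged 4.98 ± 0.36 (SD, n = 3) against 2.84 ± 0.18 (SD, n = 3) and differed by 2.14 ± 0.21. Itgae was higher by 1.62 ± 0.13, Rtn1 by 1.37 ± 0.24, the protease inhibitor Serpinb1b by 1.22 ± 0.28 and Cldn1 by 1.17 ± 0.22. Lower were the antibody gene Ighg3 at -2.09 ± 0.42, complement factor Cfb at -2.0 ± 0.25, F10 at -1.92 ± 0.32, the histidine-degrading Hal at -1.91 ± 0.26 and Il22ra2 at -1.88 ± 0.25. The lower means of Crisp3 and Ighg3 lay under the filter level of 3.51, so these differences are lower bounds. The calls of Serpinb1b (adjusted p of up to 0.158 over all settings), Ighg3 (up to 0.0817) and Cldn1 (0.0555 without DSS CD103-CD11b+ replicate 6) were lost when 1 array was left out. Itgam differed by -0.65 ± 0.20 (adjusted p = 0.155) and Itgax by -0.43 ± 0.16 (adjusted p = 0.296). Of 221 called genes 61 were higher and 160 lower, and the count was 97 without DSS CD103-CD11b+ replicate 6. All 221 were separated, as were 16.5% of all genes, where chance gives 10%. Macrophage genes had 12 of 22 lower and 0 higher (15 and 0 adjusted over the list alone; camera adjusted p = 3.25e-23), and complement and Fc receptors 10 of 16 lower and 0 higher (12 and 0 adjusted over the list alone; 6.8e-27). The cDC1 programme had 3 of 19 higher and 0 lower (6 and 2 adjusted over the list alone; 5.16e-05), and the cDC2 programme 3 of 17 lower and 0 higher (5 and 0 adjusted over the list alone; 4.75e-05). Cytokines had 3 of 24 lower and 0 higher (3 and 0 adjusted over the list alone; 0.0089), namely Il22ra2, Osm and Il1rn, the last of which lost its call without 1 of 5 arrays (adjusted p of up to 0.146 over all settings). Pattern recognition (3.02e-07), tissue repair and matrix (1.54e-06) and glycolysis and hypoxia (0.000239) were also lower, and these 8 calls held with an estimated correlation (highest adjusted p = 0.0488). Lower by camera alone were monocyte genes (1.05e-05, adjusted p = 0.0537 with an estimated correlation), chemokines (4.75e-05, adjusted p = 0.0601 with an estimated correlation), plasmacytoid DC (0.0218, adjusted p = 0.0657 with an estimated correlation), immediate-early and heat shock (0.0194, adjusted p = 0.232 with an estimated correlation) and interferon-stimulated genes (0.0344, adjusted p = 0.593 with an estimated correlation). Common DC (0.0124, adjusted p = 0.089 with an estimated correlation) and cell cycle genes (0.02, adjusted p = 0.375 with an estimated correlation) were higher. List calls of common DC, interferon-stimulated, cell cycle, immediate-early and heat shock, and plasmacytoid DC genes were lost without some single arrays (adjusted p of up to 0.76, for interferon-stimulated genes).

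The untreated and the DSS subset comparisons share no arrays, but a single fit set the spread of each gene for both. For CD103+CD11b- against CD103+CD11b+ cells, 296 genes were called higher in both and 262 lower in both. For CD103+CD11b- against CD103-CD11b+ cells the shared calls were 431 higher and 453 lower, and for CD103+CD11b+ against CD103-CD11b+ cells 44 higher and 113 lower. The number of genes called in opposite directions was 0 in every pair. Across genes the log2 differences of the 2 conditions correlated at 0.744, 0.819 and 0.542, and genes are not independent replicates.

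**Figure D3:**
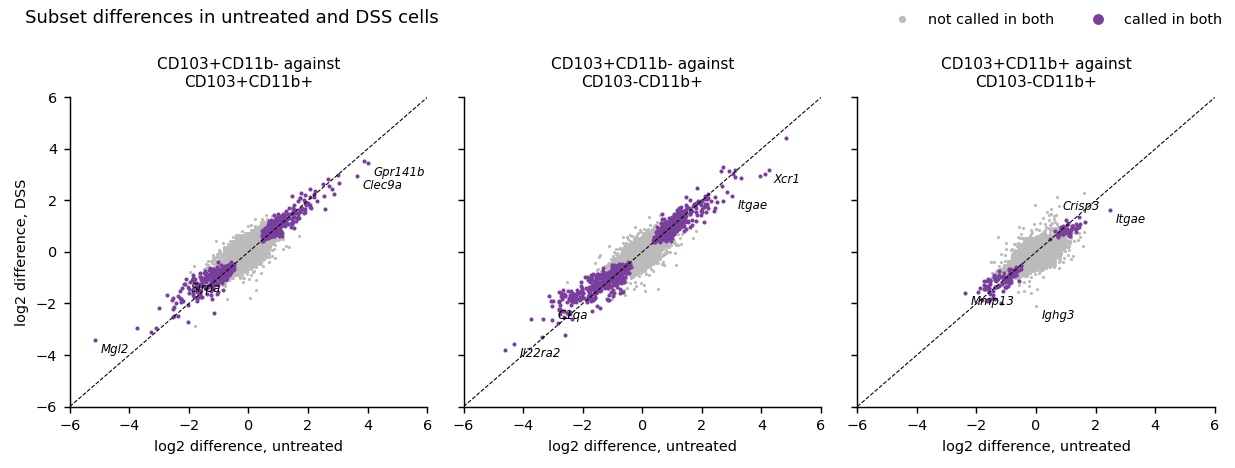
Log2 difference between subsets in DSS cells (vertical) against untreated cells (horizontal) for 14003 genes in 3 pairs of subsets, with genes called in both conditions in purple and a dashed line of equal differences. The correlation across genes was 0.744, 0.819 and 0.542.

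DSS was compared with untreated in CD103+CD11b- cells to ask what changed in this subset during colitis. Inhba, Clec4e and Serpina3n were among the genes that rose, and only the Y-linked genes Eif2s3y, Uty and Kdm5d were called lower. Inhba averaged 6.80 ± 0.28 (SD, n = 3) after DSS and 4.96 ± 0.33 (SD, n = 3) in untreated cells, a rise of 1.84 ± 0.24. Clec4e rose by 1.77 ± 0.29 and its neighbour Clec4d by 0.96 ± 0.16. The acute-phase protease inhibitor Serpina3n rose by 1.45 ± 0.19, the neutrophil-associated Retnlg by 1.33 ± 0.25, the receptor Hcar2 by 1.14 ± 0.19 and the endoplasmic reticulum protein Pdia5 by 1.13 ± 0.14. The chemokine Ccl6 rose by 1.09 ± 0.19, Igfbp5 by 1.05 ± 0.18 and transglutaminase Tgm2 by 1.03 ± 0.19. Eif2s3y fell by 3.21 ± 0.30, Uty by 1.61 ± 0.23 and Kdm5d by 1.42 ± 0.25, all lower bounds because their DSS means lay under the filter level of 3.51. Itgae differed by 0.24 ± 0.13 (adjusted p = 0.856), Itgax by 0.09 ± 0.16 (adjusted p = 0.974) and Itgam by 0.99 ± 0.20 (adjusted p = 0.084), and Itgam passed without untreated CD103+CD11b- replicate 1 (adjusted p = 0.00618). In all 18 genes were called, 15 up and 3 down, or 3 up and 3 down without untreated CD103+CD11b- replicate 3, and the count was 5 without DSS CD103+CD11b- replicate 5. Inhba, Serpina3n, Pdia5 and Eif2s3y kept their calls in every setting and Uty in every setting in which it was tested, which leaves out the stricter filter, while the other 8 named genes lost theirs when some single arrays were left out, with an adjusted p of up to 0.271 for Retnlg. All 18 were separated, as were 12.3% of all genes, where chance gives 10%.

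Lists moved in CD103+CD11b- cells after DSS although few of their genes were called. Complement and Fc receptors had 1 of 16 genes up and 0 down (4 and 0 adjusted over the list alone; camera adjusted p = 5.29e-10), Fcgr3 at 0.83 ± 0.15. Tissue repair and matrix had 2 of 22 up and 0 down (7 and 0 adjusted over the list alone; 1.41e-06), Inhba and Ptgs2 at 0.75 ± 0.14. Pattern recognition had 2 of 23 up (3 adjusted over the list alone; 3.43e-05), and the neutrophil list 2 of 15 up (5 adjusted over the list alone; 3.3e-05), with a value of 2.07 ± 0.51 for S100a9 that was not called (adjusted p = 0.242). The cDC2 programme had 1 of 17 up (7 adjusted over the list alone; 0.000125), Sirpa at 0.83 ± 0.14, and cytokines 0 of 24 (3 up adjusted over the list alone; 0.0104). B and plasma cell genes were lower with 0 of 13 called (2 down adjusted over the list alone; 0.000467). These 7 list calls held with an estimated correlation at an adjusted p = 0.0373. The gene calls of Fcgr3, Ptgs2 and Sirpa were lost on only these groups and without some single arrays (adjusted p of up to 0.192, 0.228 and 0.161). Macrophage genes were higher with 0 of 22 called (2 up adjusted over the list alone; 1.1e-06, adjusted p = 0.162 with an estimated correlation). Chemokines (0.00177, adjusted p = 0.163 with an estimated correlation), MHC class I presentation (0.00897, adjusted p = 0.198 with an estimated correlation), glycolysis and hypoxia (0.0164, adjusted p = 0.182 with an estimated correlation) and common DC genes (0.0457, adjusted p = 0.188 with an estimated correlation) were higher too. Epithelium genes were lower with 0 of 19 called (4.98e-08, adjusted p = 0.142 with an estimated correlation). Immediate-early and heat shock (4.92e-05, adjusted p = 0.0561 with an estimated correlation) and interferon-stimulated genes (0.000854, adjusted p = 0.318 with an estimated correlation) were lower with 0 of 23 called in each. List calls of common DC, interferon-stimulated, MHC class I, chemokine, and glycolysis and hypoxia genes were lost without some single arrays (adjusted p of up to 0.142, for common DC).

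In CD103+CD11b+ cells the same question gave 12 called genes, 7 up and 5 down, or 9 up and 3 down under either other scaling and 7 up and 13 down without untreated CD103+CD11b+ replicate 3. Crisp3 averaged 4.98 ± 0.36 (SD, n = 3) after DSS and 3.11 ± 0.43 (SD, n = 3) in untreated cells, a rise of 1.87 ± 0.21. Serpina3n rose by 1.73 ± 0.19, the protease inhibitor Serpinb2 by 1.60 ± 0.27, Retnlg by 1.44 ± 0.25, the growth factor Ereg by 1.33 ± 0.21, the eotaxin receptor Ccr3 by 1.31 ± 0.23 and Klhl41 by 1.22 ± 0.18. Eif2s3y fell by 2.85 ± 0.30, Uty by 1.40 ± 0.23, Trp53i11 by 1.17 ± 0.18, the chloride channel Ano1 by 1.14 ± 0.21 and the water channel Aqp4 by 0.78 ± 0.15. The lower means of Crisp3, Eif2s3y, Uty and Aqp4 lay under the filter level of 3.51, so these differences are lower bounds. Itgae differed by 0.22 ± 0.13 (adjusted p = 0.606), Itgam by 0.06 ± 0.20 (adjusted p = 0.948) and Itgax by -0.11 ± 0.16 (adjusted p = 0.863). A fit on only these groups called 0 genes, and the count was 5 without DSS CD103+CD11b+ replicate 6 and 20 without untreated CD103+CD11b+ replicate 3. Crisp3, Serpina3n and Eif2s3y kept their calls when any single array was left out, and the other 9 genes did not, with an adjusted p of up to 0.23 over all settings, for Ano1 and Aqp4. All 12 were separated, as were 15.5% of all genes, where chance gives 10%.

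The neutrophil list rose in CD103+CD11b+ cells after DSS, with 1 of 15 genes called (4 adjusted over the list alone; camera adjusted p = 5.17e-07, adjusted p = 0.0483 with an estimated correlation). S100a9 at 2.06 ± 0.51 and S100a8 at 2.05 ± 0.52 had the largest values but were not called. Other lists were called by camera only. Tissue repair and matrix was higher (0.00244, adjusted p = 0.182 with an estimated correlation) with 1 of 22 called, and the cDC1 programme (0.00408, adjusted p = 0.0699 with an estimated correlation) and monocyte genes (0.00451, adjusted p = 0.281 with an estimated correlation) were higher with 0 called. Lower with 0 called were epithelium (4.99e-05, adjusted p = 0.303 with an estimated correlation), immediate-early and heat shock (4.99e-05, adjusted p = 0.0766 with an estimated correlation), plasmacytoid DC (0.00558, adjusted p = 0.0723 with an estimated correlation), B and plasma cells (0.00739, adjusted p = 0.0766 with an estimated correlation) and DC maturation (0.00739, adjusted p = 0.281 with an estimated correlation). List calls of monocyte, DC maturation, and tissue repair and matrix genes were also lost without 1 array (adjusted p of up to 0.11).

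In CD103-CD11b+ cells, DSS against untreated gave 14 called genes, 10 up and 4 down, or 4 up and 7 down without untreated CD103-CD11b+ replicate 2. Inhba averaged 9.44 ± 0.40 (SD, n = 3) after DSS and 7.99 ± 0.39 (SD, n = 3) in untreated cells, a rise of 1.45 ± 0.24. The cDC1 gene Clec9a rose by 1.40 ± 0.26, Serpina3n by 1.31 ± 0.19, histidine decarboxylase Hdc by 1.18 ± 0.22, Zfp991 by 1.16 ± 0.20, the clotting factor F5 by 1.11 ± 0.21 and the arginine transporter Slc7a2 by 1.10 ± 0.20. The sort gene Itgae rose by 1.08 ± 0.13, from 6.35 ± 0.11 to 7.44 ± 0.19 (adjusted p = 0.00103, or 0.0951 on only these groups). Mfge8 rose by 0.92 ± 0.16 and the protein C receptor Procr by 0.79 ± 0.13. Eif2s3y fell by 2.97 ± 0.30, Uty by 1.42 ± 0.23, Aqp4 by 0.86 ± 0.15 and Fcrl5 by 0.77 ± 0.15. These 4 falls and the rise of Zfp991 are lower bounds, as the lower means lay under the filter level of 3.51. Itgam differed by 0.08 ± 0.20 (adjusted p = 0.963) and Itgax by 0.05 ± 0.16 (adjusted p = 0.97). The count was 6 at the stricter filter, 24 with limma-trend and 3 on only these groups. It was 5 without DSS CD103-CD11b+ replicate 4 and 29 without untreated CD103-CD11b+ replicate 1. Serpina3n and Eif2s3y kept their calls in every setting and Itgae kept it with any single array left out, while the other 11 genes did not, with an adjusted p of up to 0.51 over all settings, for Fcrl5. All 14 were separated, as were 11.5% of all genes, where chance gives 10%.

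The cDC1 programme rose in CD103-CD11b+ cells after DSS with 2 of 19 genes up, Itgae and Clec9a (7 adjusted over the list alone; camera adjusted p = 7.03e-05), and Xcr1 had a value of 0.92 ± 0.21 (adjusted p = 0.121). B and plasma cell genes were lower with 0 of 13 called (0.000706). These calls held with an estimated correlation, at an adjusted p = 0.0161 and 0.0473. Monocyte genes were higher with 0 of 16 called (7 up adjusted over the list alone; 8.94e-05, adjusted p = 0.129 with an estimated correlation), and Hp, which encodes haptoglobin, had a value of 1.76 ± 0.34 (adjusted p = 0.0504) from an untreated mean just under the filter level. Hp was called in 6 of the other settings (lowest adjusted p = 0.0189), among them the replicate block (adjusted p = 0.0393). Neutrophil (0.000137, adjusted p = 0.095 with an estimated correlation), eosinophil and mast cell (0.00733, adjusted p = 0.129 with an estimated correlation), tissue repair and matrix (0.0195, adjusted p = 0.272 with an estimated correlation) and chemokine receptor genes (0.048, adjusted p = 0.129 with an estimated correlation) were higher. Lower were epithelium (7.03e-05, adjusted p = 0.272 with an estimated correlation), whose mean difference of -0.3 was -0.1 without DSS CD103-CD11b+ replicate 5, interferon-stimulated (0.00903, adjusted p = 0.57 with an estimated correlation) and immediate-early and heat shock genes (0.0188, adjusted p = 0.272 with an estimated correlation). The mean difference of interferon-stimulated genes was -0.16, or -0.05 without DSS CD103-CD11b+ replicate 4. List calls of epithelium, interferon-stimulated, chemokine receptor, tissue repair and matrix, immediate-early and heat shock, and eosinophil and mast cell genes were lost without some single arrays (adjusted p of up to 0.446, for interferon-stimulated genes).

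**Figure D4:**
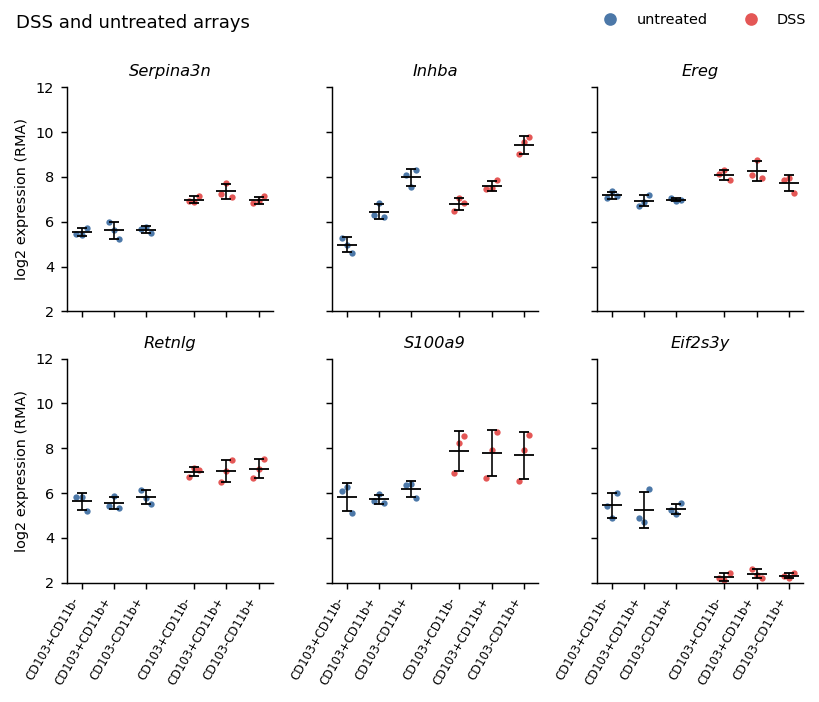
Log2 expression (RMA values) of 6 genes on each of the 18 arrays, in 3 subsets of untreated and DSS cells; points are arrays, and black marks are the mean with its SD (n = 3). Serpina3n rose by 1.45, 1.73 and 1.31 in CD103+CD11b-, CD103+CD11b+ and CD103-CD11b+ cells.

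Genes called after DSS in 1 subset are not thereby shown to differ between subsets, which the interactions tested. Of the genes called, 29 were called in 1 subset, 3 in 2 (Aqp4, Inhba and Retnlg) and 3 in all 3, where Serpina3n was higher and Eif2s3y and Uty lower. By limma, 0 genes were called in the interaction of CD103+CD11b- with CD103+CD11b+ cells, with 676 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0979. The leading genes were Mgl2 at 1.73 ± 0.30, Pdia5 at 1.07 ± 0.20 and Sirpa at 1.06 ± 0.20, and with a larger value in CD103+CD11b+ cells Crisp3 at -1.85 ± 0.30, Klhl41 at -1.21 ± 0.26 and Klrk1 at -0.81 ± 0.20. Without replicate 3, Crisp3 was called (adjusted p = 0.0265) and the count was 1. For CD103+CD11b- with CD103-CD11b+ cells limma called 0 genes, with 510 at an unadjusted p under 0.05 and a lowest adjusted p of 0.316, and 1 gene without replicate 6. Its leading genes were Pdia5 at 1.12 ± 0.20, Sirpa at 0.91 ± 0.20 and B3galt4 at 1.22 ± 0.30 on one side and Itgae at -0.84 ± 0.19, Olfr1347 at -1.12 ± 0.25 and Zfp101 at -0.67 ± 0.18 on the other. For CD103+CD11b+ with CD103-CD11b+ cells limma called 0 genes, with 778 at an unadjusted p under 0.05 and a lowest adjusted p of 0.644. There the leading genes were Crisp3 at 1.44 ± 0.30, Slc9a3r2 at 1.11 ± 0.27 and Slc22a5 at 1.02 ± 0.25, and Cdc26 at -1.41 ± 0.29, Olfr1347 at -1.17 ± 0.25 and Itgae at -0.87 ± 0.19. Crisp3 lay under the filter level of 3.51 in every group but DSS CD103+CD11b+ cells, and Zfp101 did in some groups, so the sizes of their interactions are uncertain. Itgam differed by 0.93 ± 0.29, 0.90 ± 0.29 and -0.03 ± 0.29 in the 3 interactions and Itgax by 0.19 ± 0.23, 0.04 ± 0.23 and -0.16 ± 0.23, while Itgae differed by 0.02 ± 0.19 in the first. All other settings also gave 0 calls, apart from the 2 left-out experiments named.

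Over all subsets, the means of the 3 DSS experiments were compared with those of the 3 untreated ones. Serpina3n (probe set 10398075) averaged 7.10 ± 0.10 (SD, n = 3) against 5.60 ± 0.11 (SD, n = 3), a rise of 1.5 ± 0.09 (adjusted p = 0.000296). Inhba (probe set 10403743) rose by 1.49 ± 0.13, Retnlg by 1.34 ± 0.18, Serpinb2 by 1.30 ± 0.21, the neutrophil attractant Cxcl5 by 1.04 ± 0.15, Ccr3 by 1.03 ± 0.09 and Ereg by 0.99 ± 0.14. The microRNA gene Mir103-2 rose by 0.93 ± 0.10, Hdc by 0.93 ± 0.13 and Igfbp5 by 0.91 ± 0.10. Eif2s3y (probe set 10608001) fell by 3.01 ± 0.21 (adjusted p = 0.000433), Uty by 1.48 ± 0.16, Kdm5d by 1.27 ± 0.18, the pentraxin Mptx1 by 1.06 ± 0.14 and Aqp4 by 0.73 ± 0.10. The falls of Eif2s3y, Uty and Kdm5d are lower bounds, as their DSS means lay under the filter level of 3.51. Itgae differed by 0.51 ± 0.09 (adjusted p = 0.0618) and was called with limma-trend or the replicate block (lowest adjusted p = 0.0338). Itgam differed by 0.38 ± 0.12 (adjusted p = 0.31) and Itgax by 0.01 ± 0.11 (adjusted p = 0.982). In all 26 genes were called, 21 up and 5 down, or 14 up and 6 down after quantile normalization was applied again and 9 up and 9 down without replicate 3. All 26 were separated, as were 15.9% of all genes, where chance gives 10%. A replicate block on all 18 arrays, which pairs nothing here, called 152 genes (94 up, 58 down), 25 of the 26 included. The count was 16 without a filter, 7 without replicate 5 and 31 without replicate 4. Serpina3n, Inhba, Ccr3, Mir103-2, Igfbp5 and Eif2s3y kept their calls in every setting. The other 9 lost theirs when some single experiments were left out, with an adjusted p of up to 0.157 for Serpinb2.

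Of the Y-linked genes, Eif2s3y and Uty fell in every subset, and Kdm5d was called in CD103+CD11b- cells and over all subsets. Eif2s3y averaged 5.18, 4.89 and 5.91 in untreated experiments 1 to 3 and 2.37, 2.22 and 2.37 in DSS experiments 4 to 6. Xist, which is expressed from the inactive X chromosome of females, averaged 8.79, 9.28 and 8.37 in the untreated experiments and 9.39, 9.20 and 9.22 in the DSS experiments, a difference of 0.46 ± 0.19 that was not called (adjusted p = 0.437). Xist was chosen after its values were seen. The labels give no sex of the mice, so the Y-linked falls, counted among the calls above, may reflect sex and not DSS.

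Over all subsets every list called by camera lost its call with an estimated correlation, where the lowest adjusted p was 0.187. The neutrophil list had 1 of 15 genes up and 0 down (9 and 0 adjusted over the list alone; camera adjusted p = 7.27e-08, adjusted p = 0.214 with an estimated correlation), with a value of 1.88 ± 0.40 for S100a9 (adjusted p = 0.136, or 0.00143 with the replicate block and 0.00418 without replicate 4). Tissue repair and matrix had 2 of 22 up (6 adjusted over the list alone; 1.46e-05, adjusted p = 0.214 with an estimated correlation), Inhba and Ereg. The eosinophil and mast cell list had 2 of 10 up (3 adjusted over the list alone; 0.00728, adjusted p = 0.231 with an estimated correlation), Hdc and the mast cell protease Mcpt1 at 0.79 ± 0.12, whose call was lost in 8 settings (adjusted p of up to 0.158). Monocyte (0.000354, adjusted p = 0.231 with an estimated correlation), cDC1 (0.000449, adjusted p = 0.187 with an estimated correlation), complement and Fc receptor (0.00207, adjusted p = 0.231 with an estimated correlation), pattern recognition (0.0163, adjusted p = 0.344 with an estimated correlation), chemokine (0.0187, adjusted p = 0.348 with an estimated correlation), chemokine receptor (0.0235, adjusted p = 0.214 with an estimated correlation), macrophage (0.0263, adjusted p = 0.554 with an estimated correlation), cDC2 (0.0477, adjusted p = 0.231 with an estimated correlation, 0.193 with the replicate block and 0.116 without Itgam) and cytokine genes (0.0479, adjusted p = 0.231 with an estimated correlation) were higher. Epithelium genes were lower with 0 of 19 called (3 down adjusted over the list alone; 4.72e-08, adjusted p = 0.231 with an estimated correlation). Their group means ran from 7.33 to 8.07, and carry-over of epithelial or B cells was not tested. B and plasma cell genes were lower with 0 of 13 called (5 down adjusted over the list alone; 5.35e-05, adjusted p = 0.187 with an estimated correlation), with a value of -0.56 ± 0.10 for Cd79b (adjusted p = 0.0618, or 0.0371 with limma-trend and 0.0101 with the replicate block). Immediate-early and heat shock (1.46e-05, adjusted p = 0.207 with an estimated correlation), interferon-stimulated (0.000706, adjusted p = 0.498 with an estimated correlation) and plasmacytoid DC genes (0.0184, adjusted p = 0.214 with an estimated correlation) were lower. The list calls of the cDC2 programme, macrophage, interferon-stimulated, cytokine, chemokine, chemokine receptor, pattern recognition, plasmacytoid DC, and eosinophil and mast cell genes were lost without some single experiments (adjusted p of up to 0.373, for macrophage genes).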

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

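The lists below were marked because a test of the difference between subsets in their DSS change (the interaction) was called by camera, a test planned before the results were seen. The one-share carry-over tests, with their limit for single genes, the carry-over tests with an array left out, the Xist test and the list tests with an experiment or the sort genes left out were chosen after the results were seen, and all other tests before. The rule that a high share of rising genes alone does not support carry-over was also set after.

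Between CD103+CD11b- and CD103+CD11b+ cells, the DSS change was more positive in CD103+CD11b- cells for complement and Fc receptors (camera adjusted p = 0.000192, 0.172 with an estimated correlation), the cDC2 programme (0.00317, 0.172), common DC (0.0302, 0.197), glycolysis and hypoxia (0.0302, 0.247), plasmacytoid DC (0.0302, 0.172) and pattern recognition genes (0.0456, 0.356). It was more negative for the cDC1 programme (0.0456, 0.172). All of these except complement and Fc receptors lost the call without some single experiments (adjusted p of up to 0.278). With the replicate block the macrophage (0.0337) and MHC class I lists (0.0458) were called too.

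Between CD103+CD11b- and CD103-CD11b+ cells, the DSS change was more positive in CD103+CD11b- cells for macrophage genes (camera adjusted p = 4.46e-08, 0.192 with an estimated correlation), complement and Fc receptors (5.43e-08, 0.0765), the cDC2 programme (0.00162, 0.0891) and pattern recognition (0.00162, 0.187). It was more negative for the cDC1 programme (0.001, 0.0558), monocyte genes (0.0315, 0.564) and DC maturation (0.045, 0.564). With the replicate block tissue repair and matrix was called too (0.00854). Monocyte, DC maturation and pattern recognition genes lost the call without some single experiments (adjusted p of up to 0.552). Untreated CD103-CD11b+ replicate 2 stood apart, with a mean of 8.87 against 8.27 and 8.25 for macrophage genes and 8.36 against 7.9 and 7.78 for complement and Fc receptors. Without experiment 2 the interaction was 0.2 in place of 0.38 for macrophage genes and 0.22 in place of 0.39 for complement and Fc receptors, and both stayed called (adjusted p = 0.00363 and 0.000594).

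Between CD103+CD11b+ and CD103-CD11b+ cells, the DSS change was more positive in CD103+CD11b+ cells for macrophage genes (camera adjusted p = 0.0054, 0.818 with an estimated correlation) and more negative for DC maturation (0.00323, 0.818). Both calls were lost without experiment 2 or 5 (adjusted p of up to 0.745 and 0.157), and without experiment 2 the macrophage interaction was -0.02 in place of 0.13, so its direction rests on that experiment. None of the 16 list interactions held with an estimated correlation.

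Genes of CD103-CD11b+ cells that were higher in CD103+CD11b- cells after DSS, and the reverse, were set against carry-over between the gates, although 0 genes were called in that interaction. Of 75 genes at least 2 log2 units higher in untreated CD103-CD11b+ cells, 94.7% were higher in CD103+CD11b- cells after DSS (54.4% of all genes), with a median of 0.46, and 42.7% were higher in CD103+CD11b+ cells, but the same untreated arrays chose these genes and set the level compared. With that array left out of the choice the share was at least 84.8%, and 68.6% in the other direction, so neither could tell. With the single share of carried-over cells that gives this median, 8.8%, 5.3% of the genes lay over 2 standard errors below the predicted rise, among them genes with large predictions: Cd209a at -0.26 against 0.71, Mgl2 at 1.04 against 1.78 and Il22ra2 at 0.32 against 1.14. In the other direction 75.8% of 33 genes were higher in CD103-CD11b+ cells (56.1% of all genes) and 72.7% in CD103+CD11b+ cells, and 24.2% lay below the rise predicted from a share of 6.1%, with Gpr141b at 0.33 against 1.36, Cd207 at -1.03 against 0.3 and Tssc4 at -0.3 against 0.46, whereas Itgae at 1.08 lay above its predicted 0.6, so carry-over and a change within the cells both stay open.

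The rise of the neutrophil list in all subsets was set against neutrophil RNA or cells carried into every sort alike. Over the 9 DSS arrays, 71.5% of the variance of the list's mean lay between experiments and 25.6% between subsets. This fits such carry-over, but also any effect shared by the sorts of an experiment. The lowest adjusted p of the list over the 3 interactions was 0.421, which could not tell a change within the sorted cells from carry-over. S100a9 averaged 7.89, 7.78 and 7.68 in the DSS subsets and 5.82, 5.71 and 6.18 in the untreated ones, while Ly6g, another neutrophil gene, averaged 5.79, 5.77 and 6.02 against 5.81, 6.25 and 6.24. With an estimated correlation the list's adjusted p was 0.0373 in CD103+CD11b-, 0.0483 in CD103+CD11b+ and 0.095 in CD103-CD11b+ cells and 0.214 over all subsets, the last 2 not called.

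The lower Y-linked genes in the DSS experiments were set against a different share of male mice. Xist was 0.46 higher in the DSS experiments, uncalled, and ran opposite to Eif2s3y over the 3 untreated ones. Its test met part of its prediction and alone could not tell. For the genes called over all subsets, the slope on the Eif2s3y level within the untreated experiments was -0.01 of the slope that the DSS difference needs (median of 23 genes, quartiles -0.08 to 0.13). This ratio was smaller than a different share of males would require, but the genes were called on the same experiments. A call favours a small untreated spread, and so a shallow slope, which only 3 experiments set. A part of sex in the other calls therefore stays open, also for single genes such as Serpinb2 at 0.51.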

How the results depend on the processing

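All alternatives but leaving arrays or sort genes out of the list tests were planned before the results were seen. Of 183 values for the counts, 146 stayed within 1.5 times the main count. Of 3274 values for 236 called named genes, 2960 kept their call and none changed direction, and 244 of the 314 lost calls came from leaving out an array or experiment. Of 676 values for 49 genes not called, 643 were unchanged, 14 passed and 19 changed sign. The mean of all probe sets and limma-trend lost 0 calls of named genes. Background correction and scan or slide alternatives could not be run on the deposited values. Genes tested ran from 9717 at the 60th percentile to 19937 without a filter.

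The replicate block lost 2 and gained 7 list calls and gained Itgae, Cd79b, S100a9 and Hp. It changed no other call of a named gene or list. Over all subsets it pairs nothing, as no experiment held both conditions. It fits 18 arrays there and not 6 means, so its 152 calls against 26 may overstate the evidence. Its other counts stayed within 1.5 times the main, with some genes changed (217 of 221 called again among 305 for DSS CD103+CD11b+ against CD103-CD11b+ cells).

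On only the groups of the comparison, where fewer arrays set the spread, the count was 150 for untreated CD103+CD11b+ against CD103-CD11b+ cells, 0 for DSS in CD103+CD11b+ cells and 3 for DSS in CD103-CD11b+ cells. The last was 6 at the 60th percentile and 24 with limma-trend. Without a filter, where more genes are tested, the count over all subsets was 16. With an estimated correlation 47 of 141 list calls were left. With each array or experiment left out, 88 of the 141 were kept in every run and 53 were lost in some, none with its camera direction reversed, although the mean of 1 list changed sign (macrophage, -0.02). Without Itgae, Itgam and Itgax in the cDC1, cDC2 and common DC lists, only the cDC2 call over all subsets was lost (adjusted p = 0.116). Apart from fewer arrays or more genes tested, the cause was not tested.

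Leaving out 1 array, where limma pools the spread of the remaining arrays, gave 715 to 1011 (untreated CD103+CD11b- against CD103+CD11b+), 1053 to 1267 (untreated CD103+CD11b- against CD103-CD11b+), 315 to 571 (untreated CD103+CD11b+ against CD103-CD11b+) and, in the same order after DSS, 596 to 676, 912 to 1062 and 97 to 203. For DSS against untreated the counts were 5 to 12 in CD103+CD11b-, 5 to 20 in CD103+CD11b+ and 5 to 29 in CD103-CD11b+ cells. Leaving out 1 experiment gave 0 to 1, 0 to 1 and 0 to 0 for the interactions and 7 to 31 over all subsets.

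All 19 changes of sign were in sort genes with small, uncalled differences, and the cause was not tested. With quantile normalization again, Itgax was -0.02 for DSS in CD103-CD11b+ cells and -0.007 over all subsets, Itgae was -0.054 in the interaction of CD103+CD11b- with CD103+CD11b+ cells (-0.003 centred), and Itgam was 0.075 in that of CD103+CD11b+ with CD103-CD11b+ cells. With arrays or experiments left out, Itgam ran from -0.082 to 0.187 for DSS in CD103+CD11b+ cells and from -0.043 to 0.219 in CD103-CD11b+ cells, where Itgax ran from -0.146 to 0.191 (-0.034 without DSS replicate 6). Itgae ran from -0.083 to 0.148 in the first interaction (-0.069 without replicate 4). Itgax ran from -0.095 to 0.246 in the interaction of CD103+CD11b- with CD103-CD11b+ cells (-0.041 without replicate 1). In that of CD103+CD11b+ with CD103-CD11b+ cells Itgax ran from -0.245 to 0.019 and Itgam from -0.156 to 0.181 (0.105 without replicate 3). Over all subsets Itgax ran from -0.069 to 0.102 (-0.057 without replicate 3, -0.006 without replicate 4).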

Other observations

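The tests below were planned before the results were seen, unlike the Xist test, the one-share and left-out carry-over tests and the left-out list tests. Regrouping the 6 arrays or experiments of a comparison gives 10 splits, too few for a share under 0.05. The real split gave the largest count, as 1 of 10, in each comparison with calls. The counts, with the highest of the other splits, were 960 and 0 for untreated CD103+CD11b- against CD103+CD11b+, 1447 and 1 for untreated CD103+CD11b- against CD103-CD11b+, and 575 and 2 for untreated CD103+CD11b+ against CD103-CD11b+ cells. In the same order after DSS they were 834 and 0, 1195 and 0, and 221 and 0. For DSS against untreated they were 18 and 0 in CD103+CD11b-, 12 and 1 in CD103+CD11b+ and 14 and 1 in CD103-CD11b+ cells, and 26 and 7 over all subsets. In the 3 interactions all 10 of 10 splits gave a count as large, which was 0.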
